A study of Homo sapiens with 4 samples.

How the data were processed

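Polyadenylated RNA was sequenced from BLaER1, a human B cell leukaemia line that carries an inducible C/EBPα transgene and can be converted into macrophage-like cells. The labels give 2 control libraries and 2 libraries after knockdown of HAL7, numbered replicate 0 and replicate 1 in each group, and do not say whether replicates came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Per the labels' protocols, 3 LNA GapmeRs complementary to HAL7 were added to the medium without transfection. GapmeRs are antisense oligonucleotides with a central DNA stretch that directs RNase H to the bound RNA. What the control cells received, the duration of treatment and the GapmeR sequences are not given in the sources used here. Per the labels' protocols, libraries were made from 1 µg of total RNA with the TruSeq mRNA kit; strand-specific counting is not stated.

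The table analysed holds 1 value per library for 43450 Ensembl gene IDs. The unit is not written in it. The deposited values were read as FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, because the ID column carries the name Cuffdiff gives it, Cuffdiff is among the tools in the submitters' processing notes, and the values are not whole and sum to 812554 to 853609 per library. Per the submitters' processing notes, Bowtie2 2.2.5, TopHat2 2.0.14 and Cuffdiff 2.2.1 were used with the build hg19. Their options, the gene annotation and the library scaling are not given in the sources used here. Some values of 0 look like failed estimates: EEF1A1 and MT-CO1 are listed at 0 in all 4 libraries, and MT-CO3, MT-ATP6 and MT-ATP8 at 12730, 5393 and 12209 FPKM in control replicate 0 and at 0 in the other 3 libraries. A value of 0 is therefore described only as listed at 0.

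Gene names were looked up by Ensembl ID in GENCODE release 29 and in tables of current and older symbols. Of the 12935 genes tested, 12499 (96.6%) had a name. Positions are those of GENCODE 29 on GRCh38, not on the authors' build, and serve only to say where a gene lies, which genes neighbour HAL7 and how long a gene is. The neighbour comparison had been planned with positions of the authors' build, for which no annotation was used here.

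Read depth is not stated, but low FPKM values keep a trace of it. In 1214 genes with a single annotated transcript of at least 2500 nt, the product of FPKM and transcript length in kb fell on steps, as whole fragments would give. The step was 0.0166 in control replicate 0, 0.00782 in control replicate 1, 0.00932 in knockdown replicate 0 and 0.0104 in knockdown replicate 1. Of the low values, 78.6% to 90.0% lay within 0.15 of a whole multiple, where 30% would by chance. The steps correspond to 60.3, 128, 107 and 95.8 M fragments if the authors' scaling left totals unchanged. Relative depths were 1, 2.12, 1.78 and 1.59 in the same order. Whole counts were not rebuilt for other genes, because the transcript lengths the authors used are unknown.

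Knockdown was compared with control in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1), over genes with a mean of at least 1 FPKM across the 4 libraries plus HAL7, with a mean-variance trend in the empirical Bayes step, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes; ratios are of mean FPKM. An exact permutation test of 2 libraries against 2 cannot reach significance, so the spread was pooled across genes. Of 29 gene lists with 883 entries, of which 860 matched a gene ID, 27 had at least 5 tested genes and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives.

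The lists, tests, other settings to be tried and the rule for naming genes were set before the data were examined. The rule names HAL7; its tested neighbours within 500 kb, the nearest 6; genes past the threshold, up to 12 per direction by size of change, filled up to 5 by p where fewer passed; up to 4 genes of smallest p in each list past its test; and the 2 most abundant genes of every other tested list. Some genes that the rule or a count covers are not reported here. Genes outside the rule are marked where they are named and were chosen after their values were seen, with some exceptions. Not marked are genes named for being listed at 0, RPL12 and PPIA, CTSG and GP9, and macrophage markers from a set fixed beforehand. These settings were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, quantile normalization, median centring, no variance trend, the replicate number as a block, leaving out each library, and other thresholds. Where a library was left out, the lone library of its group was assumed to vary like the other group. Chosen after seeing the data were removal of each library's trend with GC content, protein-coding genes only, weights by recovered depth, and leaving out the 4 genes listed at 0 in a library and at 10 FPKM or more in another.

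The procedure was tested on simulated data for the comparison of knockdown with control. Over 5 runs of 12935 genes with 200 changed genes, it called 69.6% of genes changed by 0.5, 98.2% of those changed by 1 and 100% of those changed by 2 on the log2 scale, with 9.8 false calls per run. A list shifted by 0.14 was called in 5 of 5 runs, with 0 false list calls. Genes were simulated independently of each other, so the runs do not test camera on lists whose genes vary together. In the data the estimated correlation between genes was 0.74 for the ribosome biogenesis list and -0.09 for the macrophage list.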

Results

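RNA from BLaER1 cells was sequenced in 2 control libraries and 2 libraries from cells exposed to GapmeRs against HAL7, a long non-coding RNA, to find the expression changes that follow its knockdown. Each library had 12902 to 12974 genes at 1 FPKM or more. Depth recovered from the steps of low values was lowest in control replicate 0 and 1.59 to 2.12 times as high in the other libraries. Correlations between libraries on the log2(FPKM + 1) scale, across genes, which are not independent replicates, ran from 0.985 between control replicate 0 and knockdown replicate 1 to 0.995 between the knockdown libraries. Control replicate 0 correlated at 0.990 with control replicate 1, which correlated at 0.994 and 0.993 with knockdown replicates 0 and 1. These values include MT-CO3, MT-ATP6 and MT-ATP8, listed at 0 in every library except control replicate 0. Such genes lower the correlations of that library. None were computed without them, so whether control replicate 0 otherwise stands apart is not known.

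HAL7 was lower in both knockdown libraries than in both control libraries, but the difference did not pass the test. Its level was 0.726 and 0.613 FPKM in control replicates 0 and 1 and 0.475 and 0.347 FPKM in knockdown replicates 0 and 1. The means were 0.670 ± 0.0804 FPKM and 0.411 ± 0.0906 FPKM (SD, n = 2 each), a ratio of 0.614, with a log2 change of -0.24 ± 0.11 (SE) and a limma adjusted p of 0.32. Its unadjusted limma p was 0.059. The 1 added to each FPKM exceeds every HAL7 value, so the log2 change understates the fall. HAL7 (ENSG00000228427.1) lies on the minus strand of chromosome X, from 71183559 to 71198175 on GRCh38, with exons at 71197909 to 71198175 and 71183559 to 71184017, a transcript of 726 nt and the annotation antisense. At the recovered depths, and over that full length, the values stand for 31.8, 56.9, 37.0 and 24.1 fragments, so the depth leaves a wide error on the size of the fall.

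The clearest changes lay in genes elsewhere in the genome. Of 12935 genes tested with limma, 4 passed an adjusted p of 0.05, of which 3 fell and 1 rose in knockdown libraries. ASIC2, which encodes a subunit of acid-sensing ion channels, fell from 5.04 ± 0.0727 to 1.15 ± 0.0261 FPKM (SD, n = 2 each), a ratio of 0.228, with a log2 change of -1.49 ± 0.08 (SE) and a limma adjusted p of 0.0069. This protein-coding gene (ENSG00000108684.9) spans 33013087 to 34174964 on chromosome 17. TRAPPC9, which encodes a subunit of a vesicle tethering complex, fell from 11.7 ± 0.189 to 5.08 ± 0.444 FPKM, a ratio of 0.433, with a log2 change of -1.07 ± 0.07 (SE) and a limma adjusted p of 0.019. TRAPPC9 (ENSG00000167632.10) is protein-coding and spans 139727725 to 140458579 on chromosome 8. TRAPPC9 lost its call without control replicate 0, at a limma adjusted p of 0.064, and without control replicate 1, at 0.061.

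The other called genes were pseudogenes, whose values are uncertain where near-identical copies share reads. Whether reads were shared was not tested for RPL12P4 or IGHV1-67 themselves. RPL12P4, a processed pseudogene of a ribosomal protein gene on chromosome 20, from 55074644 to 55075140, fell from 3.77 ± 0.361 to 0.473 ± 0.262 FPKM, with a limma adjusted p of 0.033. It lost the call without control replicate 0, at an adjusted p of 0.064 in limma, without control replicate 1, at 0.13, with a pseudocount of 0.1, at 0.14, with quantile normalization, at 0.10, and without the variance trend, at 0.054. IGHV1-67, an immunoglobulin heavy chain variable pseudogene on chromosome 14, from 106680603 to 106681042, was listed at 0 and 0.170 FPKM in control libraries and rose to 3.08 and 2.47 FPKM in knockdown libraries, with a limma adjusted p of 0.019, and lost the call with a pseudocount of 0.1, at 0.14. Without a filter on low values, 0 of the 4 genes were called, each at a limma adjusted p of 0.43. Leaving out a library changed which genes were called. Without control replicate 1 the calls included MT-CO3, MT-ATP6 and MT-ATP8, whose values of 0 look like failed estimates.

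**Figure D1:**
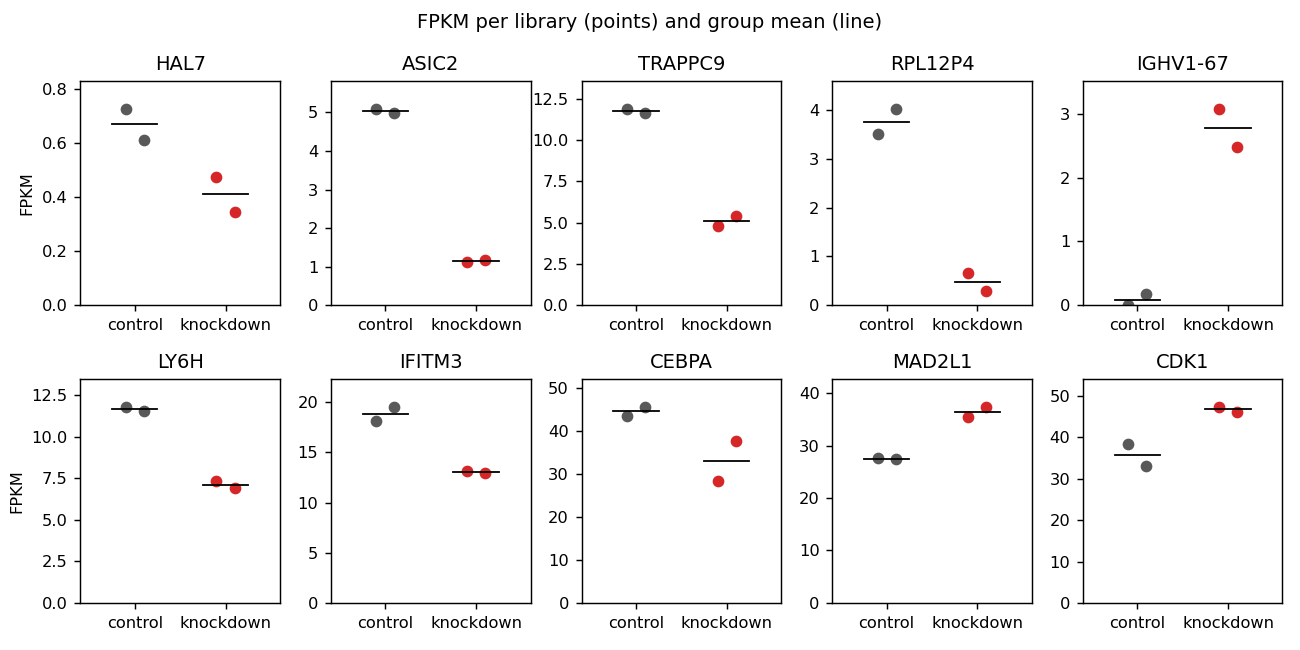
FPKM per library (points; vertical axes in FPKM, each starting at 0) and group means (lines) in control and knockdown libraries for HAL7, the called genes ASIC2, TRAPPC9, RPL12P4 and IGHV1-67, and LY6H, IFITM3, CEBPA, MAD2L1 and CDK1. The knockdown mean of ASIC2 stands at 0.228 of its control mean, that of TRAPPC9 at 0.433 and that of HAL7 at 0.614.

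Genes of next smallest p did not pass in the main fit. LY6H, which encodes a membrane-anchored protein of the Ly6 family, had 11.7 ± 0.180 FPKM in control and 7.12 ± 0.287 FPKM in knockdown libraries, with a limma adjusted p of 0.066; among protein-coding genes only, chosen after seeing the data, it was called at 0.031. IFI30, which encodes a lysosomal thiol reductase of antigen processing, had 39.5 ± 0.846 and 28.3 ± 0.608 FPKM, with a limma adjusted p of 0.13. The processed pseudogene PPIAP22 had 23.2 ± 0.806 and 45.8 ± 5.89 FPKM, with a limma adjusted p of 0.066, and was called without knockdown replicate 0, at 0.012, and without knockdown replicate 1, at 0.029. The centromere protein genes CENPQ and CENPK stood at 7.74 ± 0.322 and 11.3 ± 0.504 FPKM and at 19.3 ± 0.155 and 25.3 ± 0.111 FPKM, and MAD2L1, a spindle checkpoint gene, at 27.5 ± 0.126 and 36.4 ± 1.41 FPKM, each with a limma adjusted p of 0.16. At an unadjusted p under 0.05, limma gave 2148 genes (16.6%), 938 higher and 1210 lower, where 647 would be reached with no change in any gene. The 2 groups did not overlap in 50.3% of genes, against 33.3% by chance. Log2 changes were lower in genes of higher transcript GC content, with a Spearman rho of -0.43 across 12499 genes, which are not independent replicates. With the GC trend removed, a setting chosen after seeing the data, 1712 genes had an unadjusted limma p under 0.05, 723 higher and 989 lower.

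Near HAL7, 28 listed genes lay within 500 kb and 14 were tested. Of these, 0 passed in limma over all genes and 0 over the neighbours alone, and 3 had an unadjusted p under 0.05. MED12, a Mediator subunit gene, had 30.5 ± 0.173 FPKM in control and 26.7 ± 2.09 FPKM in knockdown libraries, and IL2RG, the common gamma chain of several cytokine receptors, had 125 ± 0.464 and 110 ± 4.49 FPKM, both with a limma p of 0.19 adjusted over the neighbours. SLC7A3, an amino acid transporter gene named outside the rule, was on the higher side, with 19.7 ± 0.670 and 21.7 ± 0.132 FPKM and a limma p of 0.22 adjusted over the neighbours. NLGN3, the nearest, stood at a knockdown-to-control ratio of 0.920. ZMYM3, CXorf65 and FOXO4, the last a forkhead transcription factor gene, stood at 0.935, 0.874 and 0.949. Without control replicate 0, 1 neighbour was called, the pseudogene RPS23P8, named outside the rule.

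Gene lists of proliferation and growth lay higher in knockdown libraries, and lists of macrophage and monocyte, interferon response, MHC class I and lysosomal genes lay lower. Of 27 lists, 10 passed camera at an adjusted p of 0.05, 6 higher and 4 lower. With an estimated correlation 0 of these 10 passed, at a camera adjusted p of 0.72 to 0.79. Correlation between genes was not the only reason. The macrophage, MHC class I and lysosome lists had estimates of -0.09, -0.06 and 0.0011, under the preset 0.01, and lost their calls too. The fit leaves 2 residual degrees of freedom, which gives camera with an estimated correlation little power. Its outcome therefore does not show that the lists did not move. Within these 10 lists, 0 genes passed limma's test over all genes. The count of lists fell to 5 without knockdown replicate 1, of which 4 were among the 10.

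G1/S and DNA replication genes had positive log2 changes in 37 of 41 tested genes, with a median of 0.14 and a camera adjusted p of 2.8e-10 (adjusted p = 0.72 with an estimated correlation). In limma 0 passed over all genes and 0 adjusted over the list alone, and 19 had an unadjusted p under 0.05, all higher. MCM6, a subunit of the replicative helicase, had 28.0 ± 0.311 and 34.7 ± 1.83 FPKM, and PRIM1, a DNA primase subunit gene, 32.0 ± 1.52 and 39.0 ± 1.48 FPKM. RFC3 and RFC5, clamp loader subunit genes, stood at ratios of 1.18 and 1.16. G2/M and mitosis genes had positive log2 changes in 43 of 45, with a median of 0.09 and a camera adjusted p of 2.3e-09 (adjusted p = 0.72 with an estimated correlation). Over all genes 0 passed, and 8 rose when adjusted over the list alone: MAD2L1, CDK1, CKS2, HMMR, CCNA2, KIF11, NUF2 and TTK, the last 4 named outside the rule. CDK1, the mitotic cyclin-dependent kinase, rose from 35.7 ± 3.80 to 46.8 ± 0.819 FPKM and CKS2, which binds it, from 130 ± 9.20 to 165 ± 10.0 FPKM, with a limma p of 0.031 adjusted over the list alone. HMMR, a spindle protein gene, rose from 13.1 ± 0.199 to 16.0 ± 0.760 FPKM by the same adjustment.

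Replication-dependent histone genes, whose transcripts mostly lack the poly(A) tail that the libraries select, were positive in 11 of 11 tested genes, with a median of 0.33 and a camera adjusted p of 8.8e-05 (adjusted p = 0.72 with an estimated correlation). Over all genes 0 passed, and 1 rose when adjusted over the list alone, H2AC6, from 11.4 ± 0.243 to 13.9 ± 0.456 FPKM, with a limma p of 0.040. H2BC4, H1-2 and H2BC5 stood at ratios of 1.63, 1.21 and 1.27. Ribosome biogenesis genes and MYC targets were positive in 38 of 39, with a median of 0.10 and a camera adjusted p of 2.9e-06 (adjusted p = 0.77 with an estimated correlation), and 0 passed in limma over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. The nucleolar protein genes NOP58, GAR1 and NCL stood at ratios of 1.15, 1.20 and 1.12 and TFB2M, a mitochondrial transcription factor gene, at 1.12. Without knockdown replicate 1, the histone and ribosome biogenesis lists had camera adjusted p of 0.067 and 0.26.

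Cytosolic ribosomal protein genes had a median of 0.04 over 78 genes and a camera adjusted p of 0.025 (adjusted p = 0.79 with an estimated correlation), with 0 past limma over all genes or adjusted over the list alone, and 0 at an unadjusted p under 0.05. RPL9, RPL5 and RPS3A stood at ratios of 1.11, 1.08 and 1.09 and RPS2 at 0.915. Heat shock protein genes had a median of 0.09 over 16 genes and a camera adjusted p of 0.040 (adjusted p = 0.77 with an estimated correlation), with 0 past limma over all genes or adjusted over the list alone and 4 at an unadjusted p under 0.05. The chaperone and co-chaperone genes HSPH1, HSP90AA1, DNAJA1 and HSPA8 stood at ratios of 1.25, 1.15, 1.17 and 1.15. Without knockdown replicate 1, the ribosomal protein list turned to the lower side with a camera adjusted p of 0.86, and the heat shock list had 0.36. The ribosomal protein list had a camera adjusted p of 0.10 without control replicate 1, the heat shock list 0.16 without control replicate 0, and with quantile normalization they had 0.24 and 0.063.

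**Figure D2:**
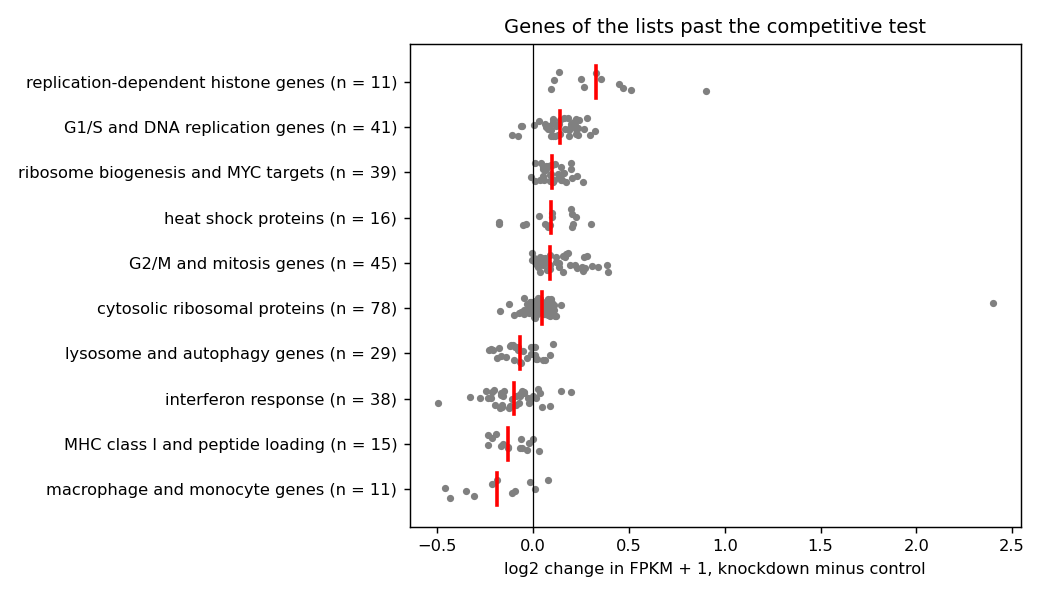
Log2 change in FPKM + 1, knockdown minus control (horizontal axis), of each tested gene (grey points) in the 10 lists past camera's test (rows, spread vertically for visibility); red bars are list medians and n counts tested genes. Medians run from -0.19 for macrophage and monocyte genes to 0.33 for histone genes; the ribosomal protein list turned to the lower side without knockdown replicate 1.

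Macrophage and monocyte genes were mostly low, with 11 of 39 matched genes tested, 9 of these negative, a median of -0.19 and a camera adjusted p of 0.0033 (adjusted p = 0.72 with an estimated correlation). Over all genes 0 passed, and 4 fell when adjusted over the list alone. CEBPA fell from 44.5 ± 1.49 to 33.0 ± 6.59 FPKM and the related factor gene CEBPB from 20.4 ± 2.83 to 14.6 ± 2.09 FPKM; reads of CEBPA from the transgene and the cell's own gene were not told apart here. SPI1, which encodes the lineage factor PU.1, fell from 54.6 ± 1.18 to 46.9 ± 0.369 FPKM, also by the list-alone adjustment. SPI1 is also expressed in B cells. The log2 change of CEBPA was -0.43 from all libraries, -0.24 without knockdown replicate 0 and -0.63 without knockdown replicate 1. The markers CD14 and LYZ had control means of 0.170 and 0.0670 FPKM.

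Interferon response genes had negative log2 changes in 31 of 38, with a median of -0.10 and a camera adjusted p of 0.0024 (adjusted p = 0.77 with an estimated correlation). Over all genes 0 passed, and 1 fell when adjusted over the list alone, IFITM3, an antiviral membrane protein gene, from 18.9 ± 0.974 to 13.0 ± 0.126 FPKM, with a limma p of 0.0046. ISG15 and IRF1 stood at ratios of 0.823 and 0.889 and LGALS3BP, a secreted galectin-binding protein gene, had 34.3 ± 0.105 and 30.2 ± 0.239 FPKM. MHC class I and peptide loading genes were negative in 13 of 15, with a median of -0.13 and a camera adjusted p of 0.0023 (adjusted p = 0.72 with an estimated correlation), with 0 past limma over all genes or adjusted over the list alone and 7 at an unadjusted p under 0.05. HLA-C stood at a ratio of 0.863, and the regulator gene NLRC5, the aminopeptidase gene ERAP1 and the transporter gene TAP1 at 0.873, 0.845 and 0.888. Lysosome and autophagy genes were negative in 20 of 29, with a median of -0.07 and a camera adjusted p of 0.039 (adjusted p = 0.72 with an estimated correlation), with 0 past limma over all genes or adjusted over the list alone and 5 at an unadjusted p under 0.05. ULK1, an autophagy kinase gene, CTSB, NPC2 and NEU1 stood at ratios of 0.853, 0.862, 0.850 and 0.881. Without knockdown replicate 1, the interferon and lysosome lists had camera adjusted p of 0.30 and 0.21, and the lysosome list had 0.068 without control replicate 0, 0.070 without control replicate 1 and 0.063 with quantile normalization.

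The other 17 lists did not pass camera, and in each of them 0 genes passed limma over all genes. B cell and pre-B cell genes, which mark the line's identity, had a median of -0.04 over 32 genes and a camera adjusted p of 0.58; DNTT, the terminal transferase gene, and IGLL1, a surrogate light chain gene, stood at ratios of 0.975 and 0.996. Cholesterol synthesis and uptake genes had a camera adjusted p of 0.065, and 4 enzyme genes named outside the rule, SQLE, CYP51A1, MSMO1 and SC5D, rose to ratios of 1.21, 1.22, 1.38 and 1.29 when adjusted over the list alone, while FDFT1 and IDI1 stood at 0.974 and 1.06. This list was called higher without control replicate 0, at a camera adjusted p of 0.016, and without knockdown replicate 0, at 0.021, and also with 3 of the settings chosen after seeing the data, at 0.032 with the GC trend removed, 0.048 among protein-coding genes only and 0.045 with depth weights. T cell and NK cell genes had a camera adjusted p of 0.065, and were called lower without knockdown replicate 0, at 0.016; NKG7, a cytotoxic granule gene named outside the rule, fell from 27.3 ± 0.331 to 19.5 ± 3.32 FPKM when adjusted over the list alone, and IL7R and ZAP70 stood at 0.947 and 0.928. Among p53 targets, with a camera adjusted p of 0.56, MDM2 and PMAIP1 rose to ratios of 1.32 and 1.21 and PHLDA3 fell to 0.821 when adjusted over the list alone, the last 2 named outside the rule, and CCNG1 stood at 0.884.

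Mitochondrially encoded genes had a median of 0.10, a mean of -1.55 that the genes listed at 0 in 3 libraries set, and a camera adjusted p of 0.076 in the higher direction, with MT-CO2 and MT-ND4L at ratios of 1.04 and 1.21. The direction of this list turned with single control libraries: it was called lower without control replicate 1, at a camera adjusted p of 0.0041, and higher without control replicate 0, at 0.0046. Among settings chosen after seeing the data, it was called higher without the genes listed at 0, at 0.0022, and with depth weights, at 0.026. Immediate early genes had a camera adjusted p of 0.11, with MYC at 377 ± 15.3 and 416 ± 46.5 FPKM and DUSP1 at a ratio of 0.939, and fatty acid synthesis genes 0.20, with ELOVL5 at 118 ± 0.944 and 127 ± 5.59 FPKM and SREBF1 at a ratio of 0.968. Integrated stress response genes had 0.44, with ATF4 and ATF5 at 0.981 and 0.889. The camera adjusted p was 0.58 for hypoxia and glycolysis, NF-kB, oxidative stress, MHC class II, plasma cell, unfolded protein response and apoptosis lists. Their most abundant genes stood at ratios of 0.997 for GAPDH and 1.08 for ENO1, 0.949 for TNFAIP3 and 1.03 for NFKBIA, 1.12 for PRDX1 and 0.897 for FTL, 1.02 for CD74, 0.990 for MZB1 and 0.929 for SSR4, 0.960 for CALR and 1.03 for HSP90B1, and 0.997 for MCL1 and 0.926 for BCL2L1. HLA-DRA had 1415 ± 35.4 and 1515 ± 57.1 FPKM. Nuclear-encoded oxidative phosphorylation genes had 0.72, with COX7C and UQCRH at 1.08 each; this list was called higher without knockdown replicate 0, at a camera adjusted p of 0.032, and lower without knockdown replicate 1, at 0.0030. Genes of RNase H and antisense oligonucleotide handling had 0.96, with NPM1 and NCL at 1.01 and 1.12. Granulocyte progenitor and erythroid and megakaryocyte lists had 3 and 2 genes past the filter and were not tested; their most abundant genes, CTSG and GP9, had means of 19.1 and 3.69 FPKM over the 4 libraries.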

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

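The alternatives named in the methods as chosen after seeing the data are included here. HAL7 stayed lower without passing under all 16 alternatives that refit it, with log2 changes of -0.598 to -0.0673 and limma adjusted p of 0.22 to 0.71. The count of called genes was 2 with a pseudocount of 0.1 (0 higher), 1 with a mean of at least 5 FPKM (0 higher, 1 lower) and, in limma without a filter, 0 (0 higher, 0 lower), where 28016 genes were tested and 3002 had an unadjusted p under 0.05. It was 6 at an adjusted p under 0.1 (2 higher) and 3 among protein-coding genes only (0 higher). Leaving out a library gave 11 to 22 called genes, 2 to 11 higher and 1 to 11 lower. With the replicate block 19 genes were called, 10 higher and 9 lower, the 4 calls made without it and LY6H (limma adjusted p 0.028), PPIAP22 (0.0053) and RPL9P9 among them, and 12 lists, to which the cholesterol and T cell lists were added, each at a camera adjusted p of 0.043; the numbers are not taken to pair libraries, as the labels name no shared culture or day and 2 pairs are too few, and same-numbered libraries deviated from their group means with a correlation of 0.12. ASIC2 was called in each fit except without a filter, at an adjusted p of 0.43 in limma, and with a mean of at least 5 FPKM, where it was not tested. Of the lists, 0 passed with an estimated correlation, 1 with fry (MHC class I, adjusted p 0.020), and 5 to 13 when a library was left out. With the GC trend removed, heat shock and lysosome lists had a camera adjusted p of 0.061, with median log2 changes of 0.077 and -0.068, against 0.091 and -0.068 before, so the sizes stayed close, and with depth weights the heat shock list had 0.068. Without a filter the ribosomal protein list had 0.099. G1/S, G2/M, MHC class I and macrophage lists passed in 17 of 17 camera fits with the preset correlation. These fits share the preset of 0.01 and so do not test it. The estimated correlations were 0.35 for G1/S, 0.35 for G2/M, -0.06 for MHC class I and -0.09 for macrophage genes. The MHC class I median went from -0.131 to -0.098 with the GC trend removed, at a camera adjusted p of 0.013, so GC content may account for part of its shift. Of the neighbours, 0 to 1 were called when a library was left out. Sign reversals touched only genes without a call, and the cause was not tested: with the GC trend removed the log2 change was 0.031 for GAPDH, 0.059 for IGLL1, 0.033 for MZB1, -0.041 for NPM1 and 0.022 for SREBF1; with depth weights 0.027 for GAPDH and -0.014 for NPM1; with median centring 0.0046 for GAPDH and 0.00127 for MCL1; and with quantile normalization -0.019 for CD74. Leaving out a library gave ranges across 0 of -0.208 to 0.065 for FOXO4, -0.077 to 0.0029 for FDFT1, -0.031 to 0.185 for IDI1, -0.086 to 0.083 for GAPDH, -0.024 to 0.229 for ENO1, -0.079 to 0.0053 for DNTT, -0.078 to 0.062 for IGLL1, -0.0079 to 0.087 for NFKBIA, -0.0086 to 0.077 for CD74, -0.056 to 0.025 for MZB1, -0.011 to 0.107 for HSP90B1, -0.028 to 0.018 for MCL1 and -0.049 to 0.065 for NPM1. The authors' own test was planned as an alternative and not run, since the table used here holds none. The lowest depth, in control replicate 0, limits genes near 1 FPKM and adds to the error on HAL7. The fewest HAL7 fragments over its full length were in knockdown replicate 1, 24.1 against 31.8 in control replicate 0.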

Other observations

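The tests of genes over 500 kb and of GC content in the cell cycle and macrophage lists were chosen after the result was seen. RPL9P9, a pseudogene of a ribosomal protein gene chosen after its values were seen, was at 0.440 and 10.5 FPKM in control and 146 and 157 FPKM in knockdown libraries, with a limma adjusted p of 0.19; it was called without control replicate 0 and without control replicate 1. The comparison of knockdown with control gave 2148 genes at an unadjusted limma p under 0.05, and the highest of the other 2 splits of the 4 libraries gave 218. Those splits count any difference between knockdown and control as spread, which holds their counts down, so the contrast overstates the separation. The splits are also too few for a share under 0.05.

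ASIC2 and TRAPPC9 span 1161878 and 730855 bp, and 50 of 11133 tested protein-coding genes are as long as TRAPPC9. The 42 protein-coding genes lower at an unadjusted p under 0.001 had a median span of 16.5 kb. That lay at percentile 0.11 of 10000 random sets matched on expression but not on GC content, so the percentile alone does not decide. Of the 42, 9 span over 100 kb, against 18.1% of tested protein-coding genes. Cleavage of short or spliced transcripts by the GapmeRs was not tested. GapmeR cleavage of long unspliced transcripts concerns long genes by definition, so the short spans of the other genes do not test it. It stays open for the longest genes: 4 of the 42 span over 500 kb, ASIC2, TRAPPC9 and, chosen after their values were seen, SMYD3 and LPP, against 1.0% of tested genes (Fisher's exact test, two-sided p 0.00084), but the genes that prompted this test are among them, and without ASIC2 and TRAPPC9 it is 2 of 40, with an exact p of 0.060, so these genes are too few to decide and GapmeR sequences were not analysed here. GC content was higher in the lower set, with a median of 61.3% against 49.9% in random sets. After the GC trend was removed, 0.955 of its median log2 change was kept. Single genes differed: CKB went from -0.35 to -0.22 and HIBCH from -0.52 to -0.58, both chosen after their values were seen. The set was picked by p before this removal, so the kept share does not exclude GC content as part of the cause. An effect of HAL7 loss stays open and untested.

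RPL12P4 and PPIAP22 were among the genes of smallest p, while their parent genes RPL12 and PPIA stood at ratios of 0.993 and 1.02. Replicate differences over 288 tested processed pseudogenes were 1.78 times those of protein-coding genes matched on expression (95% bootstrap interval 1.54 to 2.15). The genes were not matched on length, and a shorter transcript yields fewer fragments at the same FPKM. The ratio therefore cannot tell reads shared with near-identical copies from counting noise, and shared reads stay open for both pseudogenes. An effect of HAL7 loss on these pseudogenes stays open and untested.

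Cell cycle lists were higher and the macrophage list lower in the knockdown libraries. Of 12 fixed macrophage markers, 3 reached 1 FPKM in control libraries. That count just met the preset bound for arguing against fewer macrophage-like cells in the knockdown cultures. Control and knockdown means were 35.6 and 35.9 FPKM for CSF1R, 2.31 and 2.50 FPKM for AIF1 and 2.97 and 2.21 FPKM for CD68, the last of which goes with the explanation. Below 1 FPKM, ITGAM, CD14, LYZ and FCER1G were also lower and TYROBP was higher. S100A8 and S100A9 were listed at 0 in all libraries. The low levels argue against a large macrophage-like fraction, but cannot tell whether a small one shrank. GC content bias is argued against as the whole cause of the cell cycle part, since 0.855 of the median log2 change of its 86 genes was kept after the GC trend was removed, 0.13 before and 0.11 after. For the macrophage list 0.678 was kept, -0.19 before and -0.13 after, and the list still passed, at a camera adjusted p of 0.013, so GC content may account for part of its shift and the value does not decide. A difference in growth state between cultures that is unrelated to HAL7, and an effect of HAL7 loss, may each remain and were not tested. Effects of the GapmeRs other than on HAL7 cannot be told apart from HAL7 loss, as what the control cells received is not given. This holds for every difference between the groups described above.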
